A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

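RNA was measured in 12 libraries of Saccharomyces cerevisiae, 3 each of wild type S288c, RPD3 KO, RPD3 S418A and SWI3 S237A. Cells were grown in synthetic defined medium to an OD600 of 0.4, RNA was extracted with MasterPure, and stranded libraries were made from 600 ng of RNA, per the labels' protocols. The shared treatment text also describes 20 mM caffeine for 4 h for part of the samples, per the labels' protocols, while each of the 12 libraries used here is labelled synthetic defined medium. Reads were trimmed with Trimmomatic 0.36 and assigned with kallisto 0.44.0 against R64, per the submitters' processing notes. The strand setting of kallisto is not given in the sources used here.

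The deposited per-library files hold an estimated count for each of 6713 targets, per the file headers. The same files hold TPM, per the file headers, and the target lengths and effective lengths in bases, per the file headers. The 3 tables of comparisons against wild type were made with DESeq2, per the submitters' processing notes, and hold for each target a mean signal over all of the authors' libraries (baseMean), per the file headers. They also hold a log2 fold change with its standard error, a test score (the Wald statistic) and a p-value with its adjusted p-value, per the file headers. The mean signal is identical in the 3 deposited tables. The design formula, filters and any shrinkage of the authors' tables are not given in the sources used here. Columns not used numbered 0.

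Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, as 1 quasi-likelihood fit with robust dispersions over the 12 libraries, with TMM scaling and the default low-count filter for the groups. The filter kept 6327 targets. The 4 comparisons were each mutant against wild type, and RPD3 S418A against RPD3 KO. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors came from the edgeR test statistic and fold change. Exact permutation tests over the 20 assignments of 3 and 3 libraries were added for RPD3 and SWI3. The main choices were made before the data were examined.

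Gene lists of known yeast pathways were written before the data were examined, and tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 35 lists of a comparison. Estimated correlations were an alternative, and fry was run as well but is not used here. Member genes were also adjusted over each list alone, and where no such count is given beside a list it equalled the count over all genes or is in the tables only. Lists of mating-type genes, mitochondrially encoded genes, marker genes and transposon (Ty) frames served as checks. The transposon list was drawn again by gene product after the files were seen, because its fixed name pattern matched no target. Lists drawn by name pattern can hold other genes, such as RPP1 among the ribosomal proteins. Positions and products came from the R64 reference, which matched 6026 of the 6713 targets and not 687. Reads that fit several genes were gauged by the share of a gene's 31-base words found in other genes of the reference, and 530 genes were over 5%. The 687 unmatched targets were not searched, so sharing with them, as between NSR1 and the dubious frame YGR160W, is not counted. Transposon frames, dubious frames and overlapping or antisense genes are uncertain because their reads can fit several genes.

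The genes named were set by rule. RPD3 and SWI3 are always named, with their neighbours on the chromosome. For each comparison the rule takes the 10 largest rises and falls (5 for RPD3 S418A against RPD3 KO) among genes with an adjusted p under 0.05, a mean of at least 10 CPM and all 3 libraries on 1 side. Called lists give up to 4 members that passed with the smallest p, and other lists up to 2. HO, INO1 and IMD2 were chosen after their values were seen. Some genes that the rule names are not reported here.

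Distance from chromosome ends was studied after the falls near ends were seen. For genes with at most 5% shared words, the median of the outer 20 kb minus that of the rest of the arm was tested by sign permutation over ends with 100000 resamples. Correlations between comparisons that share the wild-type libraries were set beside 100 simulations with no changed genes.

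Total counts ran from 18.3 M to 27 M. A floor of 3 counts per library, which stands for 0.109 to 0.169 CPM, was used where a group had 0 counts. Intervals and floors of this kind cover counting error only. The method was tested on simulated data made from these counts with known changes: of genes changed 1.5-fold, 2-fold and 4-fold it recovered 76.1%, 88.1% and 98.5% for RPD3 KO, 82.1%, 92.5% and 100% for RPD3 S418A, 74.6%, 89.6% and 100% for SWI3 S237A, and 71.6%, 91.0% and 98.5% for RPD3 S418A against RPD3 KO. Calls on unchanged genes made up 3.2%, 3.5%, 8.9% and 4.7% of the calls. A list raised 1.3-fold was called in each comparison. In these simulations all groups started from the wild-type means, few genes were changed, and genes varied independently. In the real data 69.9% of genes were called in RPD3 KO and 60% in SWI3 S237A. The simulations therefore do not test scaling where most genes change, nor the preset correlation for lists whose genes vary together.

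Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a mean of at least 10 CPM, effective-length offsets, a replicate block by label number, each library left out in turn, the compared groups only, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. A run on genes with few shared words was chosen after seeing the data. The 9 alternatives given beside lists are RLE, total counts, the block and 6 left-out libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.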

Results

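Messenger RNA levels were measured by sequencing in 4 strains of Saccharomyces cerevisiae, with 3 libraries each: wild type S288c, a strain without the histone deacetylase gene RPD3 (RPD3 KO), a strain with a serine of Rpd3 replaced by alanine (RPD3 S418A), and a strain with a serine of the chromatin remodelling subunit Swi3 replaced by alanine (SWI3 S237A). All 12 libraries were labelled as grown in synthetic defined medium. Total estimated counts were 23.3, 23.9 and 20.2 M in wild type replicates 1, 9 and 17, 27, 26.9 and 24.3 M in SWI3 S237A replicates 2, 10 and 18, 22.5, 18.9 and 19.7 M in RPD3 KO replicates 4, 12 and 20, and 22.9, 22.5 and 18.3 M in RPD3 S418A replicates 3, 11 and 19. Of 6713 targets, 6327 had enough counts to be tested. Values below are means ± SD of CPM (counts scaled by library size) with n = 3 per strain, and log2 fold changes ± SE, with adjusted p-values from edgeR unless another tool is named. The edgeR p-values rest on 1 fit, so the spread between libraries of all 4 strains enters every comparison. They measure the spread between these libraries, since the labels do not say whether the 3 libraries of a strain came from separate cultures.

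The RPD3 transcript (chromosome XIV, 18001 to 19302) was absent from RPD3 KO and present in every other library. It had 0 counts in RPD3 KO replicates 4, 12 and 20, against 103.2, 109.4 and 111.9 CPM in wild type replicates 1, 9 and 17. With a floor of 3 counts per library (0.148 CPM), the transcript was at least 728-fold lower. RPD3 S418A had 113.0, 115.3 and 124.5 CPM in replicates 3, 11 and 19, a mean of 117.6 ± 6.09 against 108.2 ± 4.49 in wild type (log2 0.12 ± 0.06, adjusted p = 0.338, exact permutation p = 0.1). In SWI3 S237A, RPD3 was lower in all 3 libraries, at 90.53 ± 2.06 CPM (log2 -0.26 ± 0.06, adjusted p = 0.00546, exact permutation p = 0.1). The smallest p of an exact permutation test of 3 against 3 libraries is 0.1.

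The SWI3 transcript (chromosome X, 92053 to 94530) passed the test against wild type in RPD3 KO and in neither other mutant. It stood at 81.38 ± 7.65 CPM in wild type, 86.71 ± 1.99 in SWI3 S237A (log2 0.09 ± 0.08, adjusted p = 0.342, exact permutation p = 0.4) and 77.34 ± 6.56 in RPD3 S418A (log2 -0.07 ± 0.08, adjusted p = 0.662, exact permutation p = 0.4). It rose to 101.7 ± 3.94 CPM in RPD3 KO, in all 3 libraries (log2 0.32 ± 0.08, adjusted p = 0.0032, exact permutation p = 0.1). Of the genes beside RPD3 in RPD3 KO, AAD14 did not pass (log2 -0.03 ± 0.10, adjusted p = 0.78) and the peroxisome biogenesis gene PEX6 rose (log2 0.30 ± 0.07, adjusted p = 0.00232). Beside SWI3, RPL17B (log2 0.15, adjusted p = 0.187) and KRE9 (log2 0.02, adjusted p = 0.805) did not pass in RPD3 KO. Files of counts do not show the point mutations themselves, and the alleles were taken from the labels.

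**Figure D1:**
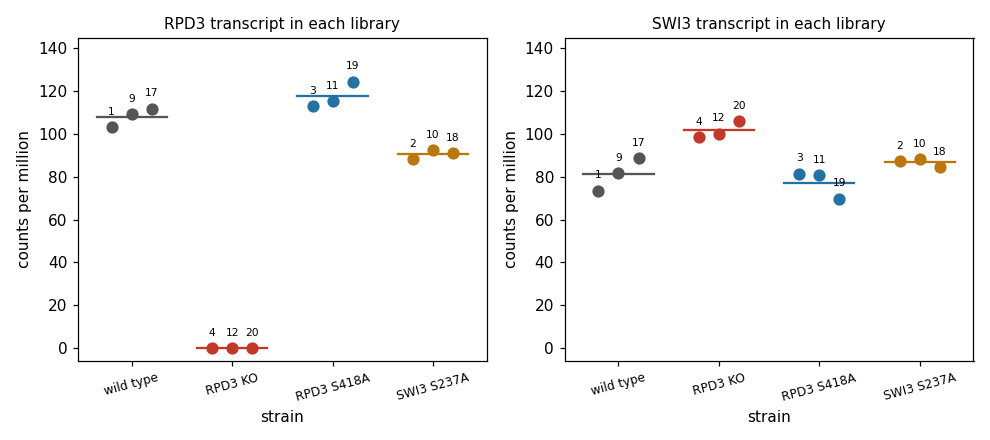
RPD3 (left) and SWI3 (right) transcript levels in CPM on the vertical axis, by strain on the horizontal axis. Each point is 1 library with its label number, each line the mean of 3 libraries, and RPD3 lies at 0 in all 3 RPD3 KO libraries.

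Genes of the mating types in wild type were those of alpha cells. MF(ALPHA)1, which encodes alpha factor, had 931 ± 56.7 CPM in wild type, and the a-factor gene MFA1 had 0.202 ± 0.0591. The marker genes MET17 and CAN1 had 0 counts in all 12 libraries. URA3 had 3 counts and LYP1 2 counts in the 3 RPD3 KO libraries together, and LYP1 had 1 count in RPD3 S418A. MET17, CAN1, URA3 and LYP1 thus had 0 counts in the strain labelled wild type, and counts do not show whether they are deleted there. LEU2 (909 ± 110 CPM in wild type) and HIS3 (117 ± 8.98) were expressed. Of 7 marker genes 5 were tested, and 1 was higher and 2 lower in RPD3 KO, 3 higher and 1 lower in SWI3 S237A, and 0 changed in RPD3 S418A. Only 1 of 18 mitochondrially encoded genes had enough counts to be tested, and it passed in no comparison.

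In RPD3 KO the nucleolar protein gene NSR1 (chromosome VII, 806412 to 807656) rose from 76.2 ± 46.6 CPM to 1430 ± 57.6 CPM (log2 4.23 ± 0.39, adjusted p = 4.59e-06), and the disaggregase gene HSP104 (chromosome XII, 88623 to 91349) fell from 6390 ± 494 to 123 ± 1.47 CPM (log2 -5.70 ± 0.09, adjusted p = 1.33e-13). In all, 4425 of 6327 tested genes changed at an adjusted p under 0.05, 2018 up and 2407 down. At least 2-fold changes were 714 up and 790 down, and at least 4-fold changes 208 up and 308 down.

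The largest rises in RPD3 KO, besides NSR1, included the helicase gene DHR2 (chromosome XI, 288845 to 291052; 5.81 ± 5.72 to 119 ± 3.4 CPM, log2 4.35 ± 0.48, adjusted p = 2.31e-05), the zinc transporter gene ZRT1 (28.9 ± 14.3 to 523 ± 17.2 CPM, log2 4.18 ± 0.28, adjusted p = 2.59e-07) and the fatty acid desaturase gene OLE1 (chromosome VII, 398628 to 400160; 101 ± 76.9 to 1800 ± 53.6 CPM, log2 4.16 ± 0.46, adjusted p = 2.33e-05). GFD2 rose 16.5-fold (8.15 ± 0.274 to 134 ± 6.22 CPM, adjusted p = 4.66e-11), SHC1, of spore chitin synthesis, 15.4-fold (adjusted p = 3.28e-09), the repressor gene TOD6 14.7-fold (adjusted p = 4.02e-06) and IZH4 14.3-fold (adjusted p = 1.69e-07). Wild type replicate 1 held 129.8 CPM of NSR1 against 45.49 and 53.23 in replicates 9 and 17, and 189.6 CPM of OLE1 against 60.32 and 52.82. Without it the log2 rises were 5.56 for DHR2, 4.86 for NSR1, 4.99 for OLE1 and 4.98 for YGR160W (4.29 with it), a dubious frame that is not in the reference used and shares the NSR1 locus. The transposon frame YLR035C-A had the largest rise (3.41 ± 1.65 to 140 ± 16.8 CPM, log2 5.36 ± 0.39, adjusted p = 4.64e-06), but 97.3% of its 31-base words occur in other genes, so its reads cannot be placed.

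The largest falls in RPD3 KO, after RPD3 itself, included HXK1, HSP30 and HXT7. The hexokinase gene HXK1 fell from 2880 ± 1290 to 29.3 ± 2.79 CPM (log2 -6.62 ± 0.36, adjusted p = 7.2e-08), the membrane heat shock gene HSP30 from 1250 ± 540 to 10.2 ± 0.879 (log2 -6.94 ± 0.31, adjusted p = 8.14e-09), and the hexose transporter gene HXT7 from 1900 ± 522 to 12.1 ± 2.45 (log2 -7.30 ± 0.27, adjusted p = 1.01e-09; 95.7% shared words). Near chromosome ends, COS10 fell from 14.7 ± 5.98 to 0.03 ± 0.0263 CPM (log2 -8.69 ± 0.50), AIF1, of cell death, from 41.7 ± 2.23 to 0.356 ± 0.203 (log2 -6.83 ± 0.18), and COS1 (log2 -6.97 ± 0.18) and COS5 (log2 -6.75 ± 0.19) fell as well, with adjusted p between 1.54e-11 and 1.95e-08. The RPD3 KO value of COS10 lies under the floor of 3 counts per library (0.148 CPM), so the size of its fall is uncertain. The acid phosphatase gene PHO11 fell by 7.09 on the log2 scale (92.6% shared words), with log2 -12.13 without RPD3 KO replicate 4 and -6.15 without wild type replicate 1. HXT15 (96.5% shared words) fell by 6.97, with log2 -7.73 without RPD3 KO replicate 12. The named genes called in any comparison had all 3 libraries outside the range of the 3 compared ones, which the naming rule largely sets, so it is no separate evidence.

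The ribosome biogenesis list, genes of the nucleolar factors that process ribosomal RNA, rose as a whole in RPD3 KO: 90 of 90 genes were higher, with a median log2 of 2.04. The camera adjusted p was 2.69e-22 (1.55e-43 to 2.32e-20 over 9 alternatives, adjusted p = 0.499 with an estimated correlation). Among its members, the helicase genes DBP7 (17.4 ± 0.74 to 109 ± 4.73 CPM, log2 2.65) and DBP8 (log2 2.55) and the processome genes IMP3 (log2 2.41) and UTP18 (log2 2.03) rose, with adjusted p from 4.53e-10 to 5.57e-09. The cytosolic ribosomal protein list was not called: 18 of 138 were higher, 15 lower and 105 not passed (9 higher and 9 lower when adjusted over the list alone), with a median log2 of 0.00 and an adjusted p of 0.582. RPS9A fell (log2 -0.59 ± 0.06, adjusted p = 2.76e-06); the list, drawn by name, also held RPP1, a subunit of RNase P, which rose (log2 1.41 ± 0.11, adjusted p = 1.75e-07). Wild type replicate 1 stood apart in the ribosome biogenesis list, with a median 0.59 above the wild-type mean against -0.28 and -0.30 in replicates 9 and 17.

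Heat shock and general stress genes were lower together in RPD3 KO than in wild type. Whether wild type stood high or RPD3 KO low cannot be told from this comparison, and a difference in culture or treatment was not tested. Of 25 chaperone genes of the heat shock factor Hsf1, 24 were lower in RPD3 KO and 0 higher. Here the median log2 was -2.32 and the camera adjusted p 2.78e-37 (1.96e-44 to 6.13e-25 over 9 alternatives, adjusted p = 0.0302 with an estimated correlation). HSP82 fell from 3620 ± 295 to 115 ± 5.73 CPM (log2 -4.98 ± 0.10), the mitochondrial chaperone gene HSP78 from 1560 ± 204 to 25.9 ± 0.918 (log2 -5.91 ± 0.11) and STI1 from 1720 ± 90.7 to 177 ± 2.77 (log2 -3.28 ± 0.07), with adjusted p of 8.62e-13, 5.59e-13 and 2.01e-12. Of 36 targets of the stress activators Msn2 and Msn4, 35 were lower. For this list the median log2 was -2.86 and the camera adjusted p 5.84e-29 (8.09e-53 to 8.06e-27 over 9 alternatives, adjusted p = 0.0981 with an estimated correlation). They included glycogen synthase GSY1 (668 ± 91.3 to 8.5 ± 0.632 CPM, log2 -6.30 ± 0.13), the trehalose genes TSL1 (log2 -4.80 ± 0.13) and TPS2 (log2 -3.44 ± 0.11), and SPI1 (log2 -5.87 ± 0.18). In the Msn2 and Msn4 list wild type replicate 1 had a median of -0.44, against 0.14 and 0.28 in replicates 9 and 17.

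**Figure D2:**
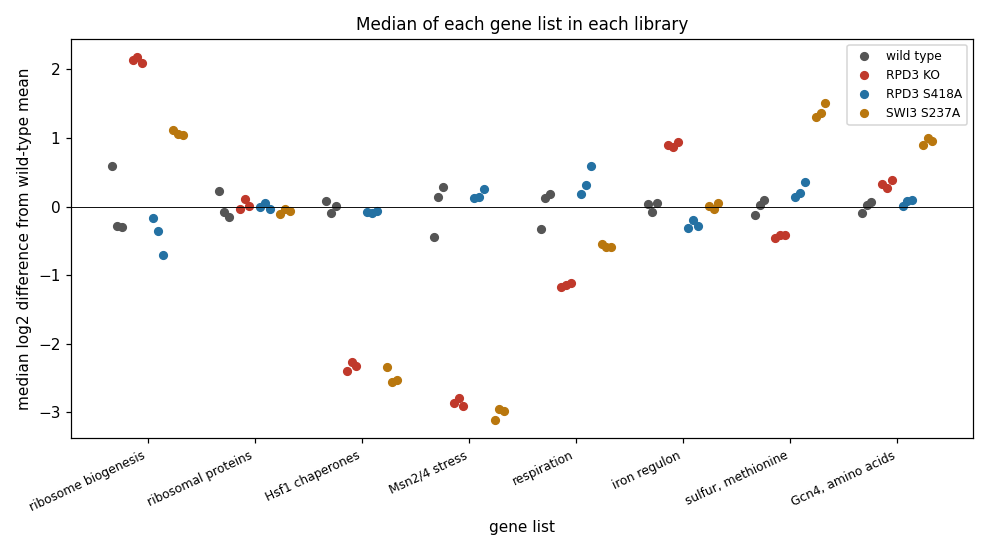
Median log2 difference from the wild-type mean (vertical axis) of 8 gene lists (horizontal axis) in each library, coloured by strain, with 1 point per library. RPD3 KO and SWI3 S237A lie together for chaperones (median log2 fold changes -2.32 and -2.61) and stress genes, and wild type replicate 1 lies apart from replicates 9 and 17 for ribosome biogenesis (0.59 against -0.28 and -0.30).

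Respiration and hexose transport also fell in RPD3 KO. Of 47 respiration genes 44 were lower and 2 higher. As a list, the median log2 was -1.17 and the camera adjusted p 2.53e-08 (2.38e-13 to 1.03e-07 over 9 alternatives, adjusted p = 0.591 with an estimated correlation). Its members included the citrate cycle genes ACO1 (1100 ± 197 to 148 ± 9.87 CPM, log2 -2.90 ± 0.12), CIT1 (log2 -2.95 ± 0.14) and IDH2 (log2 -2.59 ± 0.11) and the oxidase subunit gene COX6 (log2 -1.73 ± 0.10). Wild type replicate 1 had a respiration median of -0.32, against 0.12 and 0.19 in replicates 9 and 17. Of 16 hexose transport genes 12 were lower and 2 higher. Over all members the median log2 was -2.01 and the camera adjusted p 0.000131 (2.89e-05 to 0.000529 over 9 alternatives, adjusted p = 0.096 with an estimated correlation). HXT4 fell from 873 ± 269 to 33.4 ± 1.63 CPM (log2 -4.71 ± 0.23, adjusted p = 8.16e-09) and HXT6 from 359 ± 141 to 11.9 ± 2.13 (log2 -4.92 ± 0.30, adjusted p = 1.33e-07). Genes repressed by glucose were mixed, with 15 higher and 7 lower of 27 (16 and 7 when adjusted over the list alone; adjusted p = 0.0785), and ADH2 (log2 2.30 ± 0.13) and SIP4 (log2 2.38 ± 0.13) rose.

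Early meiotic genes, of recombination and chromosome synapsis, rose in RPD3 KO. Of 24, 20 rose and 0 fell. Across its genes the median log2 was 1.19 and the camera adjusted p 5.21e-05 (3.95e-05 to 0.0129 over 9 alternatives, adjusted p = 0.414 with an estimated correlation). MND1, of meiotic recombination, rose from 1.09 ± 0.372 to 11.8 ± 1.8 CPM (log2 3.41 ± 0.26, adjusted p = 1.34e-07), and the axis and synapsis genes ZIP1 (log2 1.64 ± 0.11, adjusted p = 3.31e-08), RED1 (log2 1.38 ± 0.10, adjusted p = 1.15e-07) and HOP1 (log2 1.15 ± 0.09, adjusted p = 2.04e-07) rose too. Mid and late sporulation genes were split, with 7 higher and 13 lower of 28 (adjusted p = 0.86), SPS1 rising (log2 2.77 ± 0.17) and SMK1 falling (log2 -1.84 ± 0.12). The repressor gene UME6 rose (58.1 ± 3.51 to 132 ± 7.15 CPM, log2 1.18 ± 0.09, adjusted p = 1.8e-07). CAR1, which encodes arginase, rose (log2 2.22 ± 0.10, adjusted p = 1.03e-09), and so did INO1, of inositol synthesis, chosen after its values were seen (10.9 ± 0.823 to 69.4 ± 3.11 CPM, log2 2.66 ± 0.08). The nitrogen list (6 higher and 9 lower of 25, adjusted p = 0.995) and the inositol and phospholipid list (9 higher and 6 lower of 19, adjusted p = 0.0819) were not called.

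Alpha-specific mating genes fell in RPD3 KO, 5 of 5. The median log2 was -2.42 and the camera adjusted p 4.96e-05 (3.48e-06 to 0.00011 over 9 alternatives, adjusted p = 0.361 with an estimated correlation). The receptor gene STE3 fell from 275 ± 20.3 to 51.2 ± 3.68 CPM (log2 -2.42 ± 0.08), MF(ALPHA)2 from 580 ± 146 to 62.3 ± 5.99 (log2 -3.22 ± 0.16), the agglutinin gene SAG1 from 854 ± 225 to 132 ± 13 (log2 -2.69 ± 0.17) and MF(ALPHA)1 from 931 ± 56.7 to 559 ± 15.5 (log2 -0.74 ± 0.06), with adjusted p from 9.17e-11 to 4.72e-07. The alpha-specific median of wild type replicate 1 was 0.37, against -0.13 and -0.20 in replicates 9 and 17. Of the a-specific genes 3 rose and 2 fell of 5 (adjusted p = 0.995), and of the haploid-specific genes 1 rose and 5 fell of 10 (adjusted p = 0.504). Of the pheromone response genes 4 rose and 12 fell of 19. The list was not called (adjusted p = 0.0572), but passed under RLE (0.0479), total counts only (0.0304) and without wild type replicate 1 (0.0244), 9 (0.0492) or 17 (0.0391) or RPD3 KO replicate 4 (0.0431). Among those that fell were PRM8 (log2 -2.38 ± 0.09) and SST2 (log2 -1.41 ± 0.10). HO, chosen after its values were seen, had 104 ± 5.2 CPM in RPD3 KO and 43.9 ± 12 in wild type. IMD2, chosen after its values were seen, had 30.9 ± 0.184 CPM in RPD3 KO and 724 ± 23.4 in wild type.

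Iron uptake, amino acid synthesis and cell cycle genes rose in RPD3 KO. In the iron regulon 20 of 26 were higher and 4 lower. Here the median log2 was 0.91 and the camera adjusted p 2.02e-06 (4.47e-07 to 1.29e-05 over 9 alternatives, adjusted p = 0.361 with an estimated correlation). Its members included the mannoprotein genes FIT1 (log2 2.53 ± 0.14) and FIT2 (56.4 ± 9.41 to 257 ± 27.7 CPM, log2 2.19 ± 0.12), the siderophore transporter gene ARN1 (log2 1.72 ± 0.11) and the reductase gene FRE1 (log2 1.63 ± 0.09). Of 44 targets of the activator Gcn4 24 were higher and 6 lower. For this list the median log2 was 0.33 and the camera adjusted p 0.0127 (0.00661 to 0.0278 over 9 alternatives, adjusted p = 0.591 with an estimated correlation). Under total counts only the Gcn4 median was 0.51. Its members included SNZ1 (log2 1.91 ± 0.11), LYS20 (log2 1.29 ± 0.09) and LEU9 (log2 1.24 ± 0.10). Of 24 G1/S genes 18 were higher and 2 lower. As a list, the median log2 was 0.72 and the camera adjusted p 0.00155 (0.000666 to 0.0283 over 9 alternatives, adjusted p = 0.516 with an estimated correlation). Its members included TOS4 (log2 1.37 ± 0.10), the cyclin gene CLB5 (log2 1.01 ± 0.09) and RAD27 (log2 0.99 ± 0.07). Of 15 G2/M genes 12 were higher (13 when adjusted over the list alone) and 0 lower. Over all members the median log2 was 0.54 and the camera adjusted p 0.00907 (0.00327 to 0.0691 over 9 alternatives, adjusted p = 0.591 with an estimated correlation). Its members included BUD4 (log2 0.94 ± 0.11), HOF1 (log2 0.86 ± 0.08) and CDC20 (log2 0.72 ± 0.05). The G2/M call ended without wild type replicate 1 (adjusted p = 0.0691).

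Genes within 20 kb of a chromosome end fell in RPD3 KO, in a test chosen after the falls there were seen. Among genes that share at most 5% of their 31-base words, the median of the outer 20 kb lay below that of the rest of the arm at 17 of 21 chromosome ends (mean difference -1.99 ± 1.96 SD over 21 ends, permutation p = 6e-05, Benjamini-Hochberg adjusted p = 0.00024). Among the 93 genes within 10 kb, 70 fell and 7 rose (median log2 -3.22), and among the 121 genes at 10 to 20 kb, 86 fell and 12 rose (median log2 -1.63). Beyond 100 kb the median was -0.04. RPD3 itself lies 10 to 20 kb from an end of chromosome XIV. It was not left out, so its fall, set by the deletion, counts among the genes within 20 kb but not among those within 10 kb. Of 29 genes within 10 kb that share at most 5% of their 31-base words, 22 fell and 4 rose. The transporter gene GIT1, 18 kb from an end of chromosome III, had 0 counts in RPD3 KO and was at least 38-fold lower. In RPD3 S418A the difference was -0.12 with 12 of 21 ends lower (permutation p = 0.26, adjusted p = 0.26), but 6 of the same 29 genes fell against 0.79% elsewhere (Fisher p = 1.5e-07, adjusted p = 1.2e-06). In SWI3 S237A the difference was 0.17 with 3 of 21 ends lower (permutation p = 0.071, adjusted p = 0.095), and of the 29 genes 14 rose (29.66% elsewhere, Fisher p = 0.04, adjusted p = 0.046) and 4 fell (32.69% elsewhere, Fisher p = 0.029, adjusted p = 0.039). Neighbouring genes are not independent, so the Fisher tests overstate the evidence.

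**Figure D3:**
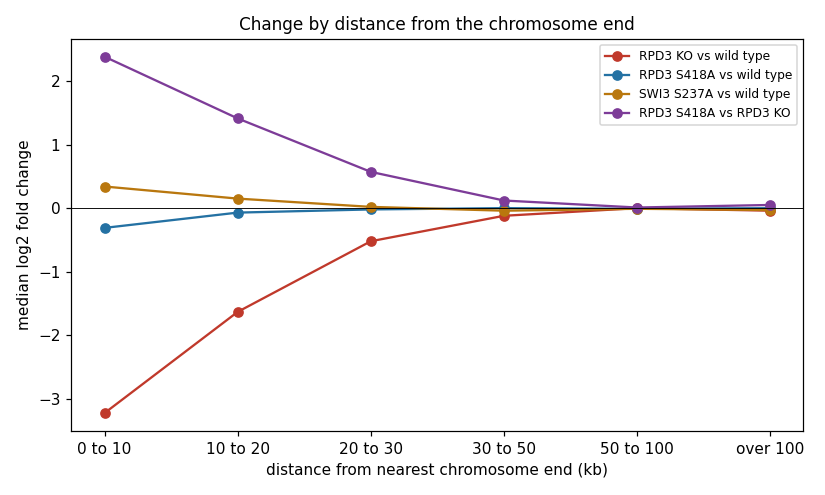
Median log2 fold change (vertical axis) of all tested genes by distance from the nearest chromosome end in kilobases (horizontal axis), with 1 line per comparison and points for the medians. In RPD3 KO the median was -3.22 within 10 kb and -0.04 beyond 100 kb.

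Of 35 gene lists tested in RPD3 KO 11 were called, 6 up and 5 down, and 1 of them, the chaperones, with an estimated correlation. Lists not called by camera still held large single changes: the cell wall protease gene YPS6 (log2 -4.55 ± 0.19), the cytochrome gene CYC7 (log2 -4.98 ± 0.25), the vitamin gene SNO2 (log2 -5.38 ± 0.27, -6.05 without RPD3 KO replicate 4), the phosphatase gene PHM8 (log2 -2.95 ± 0.09), the sulfate transporter gene SUL1 (log2 -1.71 ± 0.09) and the linker histone gene HHO1 (log2 1.19 ± 0.11). The seripauperin genes PAU18 and PAU6, whose reads are shared, each fell by 5.92 on the log2 scale, with log2 -9.51 without RPD3 KO replicate 12 and -5.30 without RPD3 KO replicate 4. Groups of RPD3 KO and wild-type values did not overlap in 4642 genes (73.4%), where 10% is the share given by chance. The split into rises and falls rests on the scaling: 45.6% of called genes were higher under TMM and 60.2% under total counts only, a median shift of 0.179 log2 units, with 26 called genes changing sign. Of the called genes 257 were not in the reference used and 270 shared over 5% of their words with other genes. The authors' deposited table called 4117 genes, 2029 up and 2088 down, of which 4004 were also called here with the same sign (Pearson r = 0.983 between log2 fold changes). That table held no adjusted p for NSR1, DHR2, OLE1, IZH4 and YGR160W. For MF(ALPHA)1 its adjusted p was 0.397 (log2 -0.69).

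In RPD3 S418A 128 of 6327 genes changed against wild type, FIT2, FIT3 and PHO84 among them. The cell wall mannoprotein genes FIT2 (chromosome XV, 1059531 to 1059992) and FIT3 (chromosome XV, 1060441 to 1061055), which help retain iron, fell from 56.4 ± 9.41 to 13.9 ± 1.1 CPM (log2 -2.03 ± 0.13, adjusted p = 7.43e-06) and from 78.3 ± 23.5 to 20.3 ± 3.65 CPM (log2 -1.95 ± 0.21, adjusted p = 0.000631). The phosphate transporter gene PHO84 (chromosome XIII, 24037 to 25800) rose from 80 ± 46.9 to 341 ± 33.8 CPM (log2 2.09 ± 0.35, adjusted p = 0.0174), with wild-type values of 129.4, 74.39 and 36.18 in replicates 1, 9 and 17. Of the changed genes 52 were up and 76 down, and 5 up and 22 down by at least 2-fold. The PHO84 call ended without wild type replicate 9 (adjusted p = 0.0591) or RPD3 S418A replicate 19 (adjusted p = 0.0567), while those of FIT2 and FIT3 held under every alternative.

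**Figure D4:**
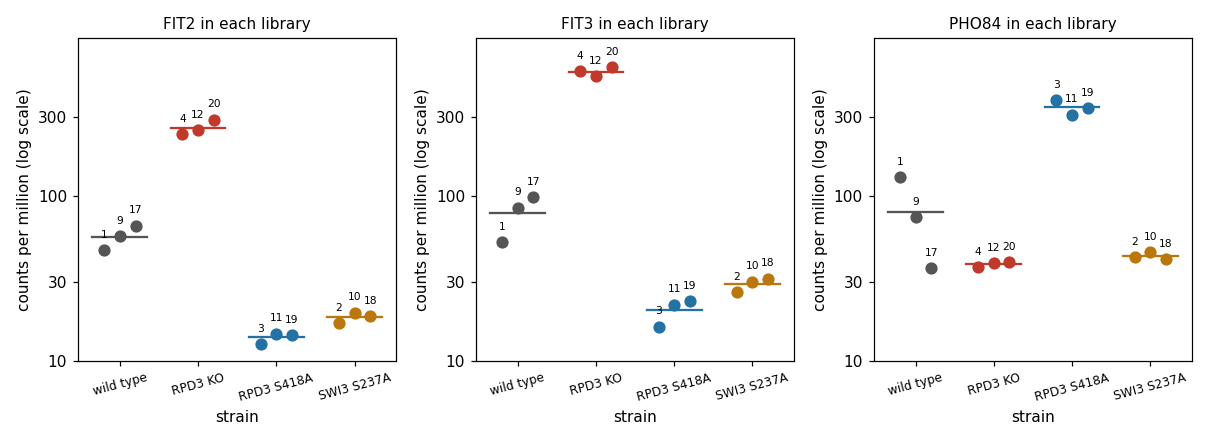
FIT2, FIT3 and PHO84 in CPM (vertical axis, log scale) by strain (horizontal axis). Each point is 1 library with its label number and each line the mean of 3, with PHO84 at 341 CPM in RPD3 S418A against 80 in wild type, and FIT2 at 13.9 against 56.4.

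In the iron regulon of RPD3 S418A 9 of 26 genes fell and 0 rose (14 fell when adjusted over the list alone). Across its genes the median log2 was -0.28 and the camera adjusted p 3.42e-24 (1.18e-26 to 5.33e-15 over 9 alternatives, adjusted p = 0.0378 with an estimated correlation). Besides FIT2 and FIT3 these included FIT1 (log2 -1.43 ± 0.16, adjusted p = 0.000575), the siderophore transporter genes ARN2 (47.8 ± 3.33 to 24.8 ± 0.761 CPM, log2 -0.94 ± 0.08, adjusted p = 4.76e-05) and SIT1 (log2 -1.39 ± 0.21, adjusted p = 0.00584), TIS11, of messenger decay under low iron (24.5 ± 1.42 to 10.9 ± 2.25 CPM, log2 -1.17 ± 0.12, adjusted p = 0.000331), and the ferroxidase gene FET3 (log2 -1.20 ± 0.25, adjusted p = 0.0406). FET3 lost its call with the compared groups only (0.301) and without wild type replicate 17 (0.07), RPD3 S418A replicate 3 (0.0752) or replicate 19 (0.157). The iron medians of the 3 RPD3 S418A libraries were -0.31, -0.19 and -0.28.

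In the phosphate list of RPD3 S418A 7 of 20 rose and 0 fell (8 and 1 when adjusted over the list alone). The median log2 was 0.29 and the camera adjusted p 5.75e-09 (4.33e-25 to 5.74e-06 over 9 alternatives, adjusted p = 0.0769 with an estimated correlation). They included the polyphosphate genes VTC3 (95.8 ± 20.5 to 167 ± 17.8 CPM, log2 0.80 ± 0.12, adjusted p = 0.00536) and VTC4 (log2 0.65 ± 0.10, adjusted p = 0.00357) and the phosphatase gene PHO8 (log2 0.29 ± 0.06, adjusted p = 0.0177), whose call ended without wild type replicate 9 (0.0688), wild type replicate 17 (0.0599) or RPD3 S418A replicate 11 (0.0926). Wild type replicates 1, 9 and 17 had phosphate medians of 0.17, -0.01 and -0.17. In the sulfur and methionine list 7 of 23 rose and 0 fell (13 when adjusted over the list alone). Here the median log2 was 0.23 and the camera adjusted p 1.16e-11 (3.77e-12 to 3e-09 over 9 alternatives, adjusted p = 0.0426 with an estimated correlation). STR3 rose from 29.6 ± 5.28 to 56 ± 2.31 CPM (log2 0.92 ± 0.10, adjusted p = 0.000575), the methionine synthase gene MET6 from 408 ± 20 to 623 ± 37.3 (log2 0.61 ± 0.07, adjusted p = 0.000612), SAM2 (log2 0.53 ± 0.07, adjusted p = 0.0021) and MHT1 (log2 0.81 ± 0.12, adjusted p = 0.00507).

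In RPD3 S418A, of 19 pheromone response genes 4 fell and 1 rose (8 and 1 when adjusted over the list alone). For this list the median log2 was -0.38 and the camera adjusted p 1.61e-05 (3.21e-06 to 0.00119 over 9 alternatives, adjusted p = 0.0426 with an estimated correlation). Its members included AGA1, of cell adhesion (76.5 ± 14.3 to 36.3 ± 3.97 CPM, log2 -1.07 ± 0.14, adjusted p = 0.00154), FIG2 (log2 -0.59 ± 0.11, 0.0538 without RPD3 S418A replicate 19), PRM4 (log2 -0.62 ± 0.12, 0.0681 without wild type replicate 17 and 0.0802 without RPD3 S418A replicate 11) and PRM1 (log2 -0.52 ± 0.11, adjusted p = 0.0272). The PRM1 call ended without wild type replicates 9 (0.0789) or 17 (0.0829) or RPD3 S418A replicates 3 (0.0539), 11 (0.0975) or 19 (0.0719). In the cell wall integrity list 5 of 22 rose (6 when adjusted over the list alone; median log2 0.17, 0.26 without wild type replicate 1 and 0.09 without replicate 17; camera adjusted p = 1.91e-05, 6.54e-10 to 0.00384 over 9 alternatives, adjusted p = 0.311 with an estimated correlation). CWP1 rose from 160 ± 11.7 to 295 ± 40.2 CPM (log2 0.88 ± 0.10, adjusted p = 0.000612), the kinase gene KDX1 from 14.1 ± 2.56 to 27.2 ± 1.33 (log2 0.95 ± 0.12, adjusted p = 0.000921), and PST1 (log2 0.43 ± 0.07) and SED1 (log2 0.45 ± 0.09) less. The SED1 call ended without wild type replicates 9 (0.0741) or 17 (0.0536) or RPD3 S418A replicates 11 (0.11) or 19 (0.115). Of the daughter separation list 1 of 15 rose, PIR3 (9.56 ± 0.641 to 21.5 ± 4.66 CPM, log2 1.17 ± 0.14, adjusted p = 0.000712; list median 0.16, 0.10 without wild type replicate 1; camera adjusted p = 0.000906, 6.69e-05 to 0.00443 over 9 alternatives, adjusted p = 0.0907 with an estimated correlation).

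Among the other large changes in RPD3 S418A, the anaerobic cell wall gene TIR1 fell from 74.4 ± 4.53 to 21.6 ± 4.94 CPM (log2 -1.78 ± 0.13, adjusted p = 2.74e-05) and DAN1 fell (log2 -1.90 ± 0.33, adjusted p = 0.0104, 0.0564 without RPD3 S418A replicate 11 and 0.0545 without replicate 19). Their list had 2 of 19 lower (3 lower and 1 higher when adjusted over the list alone; median log2 -0.15, -0.24 without RPD3 S418A replicate 3 and -0.08 without replicate 19; camera adjusted p = 0.00138, 0.000613 to 0.0236 over 9 alternatives, adjusted p = 0.311 with an estimated correlation). The methionine sulfoxide reductase gene MXR1 rose (42 ± 3.96 to 74 ± 5.73 CPM, log2 0.82 ± 0.09, adjusted p = 0.000612). The permease genes MMP1 (log2 0.97 ± 0.18, adjusted p = 0.0209, 0.0595 without RPD3 S418A replicate 11 and 0.0985 without replicate 19) and AGP1 (log2 0.85 ± 0.16, adjusted p = 0.0237, 0.0599 without wild type replicate 17, 0.0527 and 0.0681 without RPD3 S418A replicates 3 and 11) rose. HXT6 rose (log2 1.20 ± 0.25, adjusted p = 0.0425), with 0.0631 under total counts only, 0.0852 without wild type replicate 17 and 0.0667, 0.0802 and 0.146 without RPD3 S418A replicates 3, 11 and 19. Whether HXT6 rose apart from HXT7, which shares most of its words with other genes, was not tested. The subtelomeric helicase gene YRF1-1 (312 ± 8.94 to 157 ± 4.94 CPM, log2 -0.99 ± 0.08, adjusted p = 2.74e-05) and YFL066C (log2 -1.18 ± 0.23) fell, with all or nearly all of their sequence shared with other genes. The YFL066C call ended without wild type replicates 9 (0.0688) or 17 (0.07) or RPD3 S418A replicates 11 (0.0802) or 19 (0.107).

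Some lists were called in RPD3 S418A with at most 1 gene passing. Of the respiration genes 1 of 47 rose (21 when adjusted over the list alone), with a median log2 of 0.38, falling to 0.20 without wild type replicate 1 and 0.24 without RPD3 S418A replicate 19 (camera adjusted p = 1.17e-16, 6.76e-23 to 3.44e-07 over 9 alternatives, adjusted p = 0.369 with an estimated correlation). COX8 was the 1 that passed (log2 0.53 ± 0.10, adjusted p = 0.0209, 0.0893 without RPD3 S418A replicate 19). Of 90 ribosome biogenesis genes 0 passed, with a median of -0.45 that shrank to -0.10 without wild type replicate 1 (camera adjusted p = 1.99e-13, 6.76e-23 to 0.0132 over 9 alternatives, adjusted p = 0.613 with an estimated correlation). Wild type replicate 1 itself lay at 0.59 in that list and at -0.32 in respiration. The Msn2 and Msn4 list was called upward (median 0.14, GLC3 rising with log2 0.65 ± 0.09; camera adjusted p = 0.00145, 5.85e-06 to 0.865 over 9 alternatives, adjusted p = 0.658 with an estimated correlation), and its call ended without wild type replicate 1 (adjusted p = 0.865, median -0.05). Its median was 0.22 without wild type replicate 17 and 0.08 without RPD3 S418A replicate 19.

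Further lists called in RPD3 S418A were lower. In the alpha-specific list 0 of 5 passed (3 fell when adjusted over the list alone; median -0.30, camera adjusted p = 0.0273, 0.00302 to 0.219 over 9 alternatives, adjusted p = 0.61 with an estimated correlation), and the call ended without wild type replicate 1 (0.219) or RPD3 S418A replicate 3 (0.101). In the mid and late sporulation list 0 of 28 passed (2 fell when adjusted over the list alone). As a list, the median log2 was -0.35 and the camera adjusted p 0.000748 (0.000176 to 0.0314 over 9 alternatives, adjusted p = 0.206 with an estimated correlation). In the thiamine and vitamin list 1 of 22 fell, SNO2 (2 when adjusted over the list alone; log2 -0.94 ± 0.18). Over all members the median log2 was -0.19 and the camera adjusted p 0.000504 (1.18e-05 to 0.00554 over 9 alternatives, adjusted p = 0.0426 with an estimated correlation). The SNO2 call ended without wild type replicates 9 (0.0666) or 17 (0.0659) or RPD3 S418A replicates 11 (0.0709) or 19 (0.0685). The chaperone list was not called (0 of 25 passed, median -0.08, adjusted p = 0.276, but called at 0.0261 without wild type replicate 9), and neither were the early meiotic genes (0 of 24, median 0.00, adjusted p = 0.994).

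Of 35 lists 13 were called in RPD3 S418A, 6 up and 7 down, 4 of them with an estimated correlation. Without wild type replicate 1 the number of called genes rose to 272 and 7 further lists were called, the ribosomal proteins among them (median 0.13, adjusted p = 1.76e-11). Called genes numbered 60 without RPD3 S418A replicate 19, 68 without replicate 11 and 74 without wild type replicate 17. Pairs of libraries of a strain had a chi-square per degree of freedom of up to 13.22 in RPD3 KO and 16.85 in SWI3 S237A. The highest values were 45.38 in RPD3 S418A and 121.18 in wild type. With the compared groups only, which leaves RPD3 KO and SWI3 S237A out of the estimate of the spread, called genes numbered 29. Calls that ended there, with their adjusted p, were PHO84 (0.202), HXT6 (0.264), MMP1 (0.202), AGP1 (0.234), MHT1 (0.096), SIT1 (0.119), YFL066C (0.134), VTC4 (0.115), VTC3 (0.124), PHO8 (0.257), FIG2 (0.128), PRM4 (0.142), PRM1 (0.202), DAN1 (0.119), COX8 (0.161), SAM2 (0.084), PST1 (0.148), SED1 (0.164) and SNO2 (0.078). With an unadjusted p under 0.05 there were 1142 genes, and the values did not overlap in 1158 genes (18.3%, where 10% is the share given by chance). The authors' deposited table called 103 genes, 26 up and 77 down, of which 73 were also called here with the same sign (Pearson r = 0.93). Genes named above as changed that did not pass in that table, with its adjusted p, were HXT6 (0.639), PHO8 (0.513), GLC3 (0.456) and FIG2 (0.404). The same held for STR3 (0.202), PRM1 (0.187), AGP1 (0.179), MET6 (0.135) and SED1 (0.0594). Of the called genes 28 shared over 5% of their words, and 7 were not in the reference used.

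In SWI3 S237A 3799 genes changed against wild type, 1816 up and 1983 down, with 398 up and 456 down by at least 2-fold. Amino acid and sulfur genes rose, and chaperone and stress genes fell. The methionine genes MET3 (chromosome X, 456239 to 457774) and MET6 rose from 45.2 ± 2.36 to 353 ± 9.56 CPM (log2 2.96 ± 0.07, adjusted p = 1.16e-11) and from 408 ± 20 to 2580 ± 39.4 CPM (log2 2.66 ± 0.07, adjusted p = 2.77e-11). LEU1, of leucine synthesis (chromosome VII, 476313 to 478652), rose from 118 ± 10.2 to 1550 ± 26.9 CPM (log2 3.71 ± 0.09, adjusted p = 1.07e-11), and HSP26 fell from 766 ± 267 to 6.63 ± 0.155 CPM (log2 -6.85 ± 0.32, adjusted p = 3.02e-08). HO, the mating-type switching endonuclease gene (chromosome IV, 46271 to 48031), fell from 43.9 ± 12 to 3.58 ± 0.453 CPM (log2 -3.62 ± 0.23, adjusted p = 1.93e-07).

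The largest rises in SWI3 S237A were OLE1 (101 ± 76.9 to 2040 ± 23.8 CPM, log2 4.33 ± 0.47, adjusted p = 3.17e-05; 5.17 without wild type replicate 1), the serine synthesis gene SER3 (chromosome V, 322686 to 324095; 33.4 ± 8.32 to 487 ± 14.4 CPM, log2 3.87 ± 0.15, adjusted p = 4.78e-10) and LEU1. Transposon frames with 0 counts in wild type had higher values still: YDR098C-A was at least 568-fold higher, YML045W-A at least 517-fold, YDR316W-A and YGR161C-C at least 513-fold, YGR027W-A at least 507-fold, and YAR010C and YPR137C-A at least 297-fold. The call of YDR098C-A ended without any 1 of the 6 libraries (adjusted p from 0.0656 to 0.0758) and with limma-voom (0.238), and those of YDR316W-A and YGR161C-C ended without SWI3 S237A replicate 18 (0.0558). All their words occur in other genes, so the copies cannot be told apart. The strain's own transposons are not given in the sources used here. Over 61 tested transposon frames 16 were higher and 28 lower in SWI3 S237A (29 lower when adjusted over the list alone), 3 higher and 30 lower in RPD3 KO (27 lower), and 0 higher and 9 lower in RPD3 S418A (1 and 20). The largest falls, besides HSP26, were HXT7 (log2 -6.80 ± 0.26), HSP12 (154 ± 103 to 1.48 ± 0.129 CPM, log2 -6.69 ± 0.80), HSP30 (log2 -6.42 ± 0.30), DDR2 (log2 -6.36 ± 0.64), RTC3 (log2 -6.28 ± 0.26), ARO9, of aromatic amino acid breakdown (261 ± 127 to 3.92 ± 0.202 CPM, log2 -6.06 ± 0.40), EGO4 (log2 -5.95 ± 0.53) and TMA10 (log2 -5.90 ± 0.19), with adjusted p from 1.84e-10 to 6.92e-05. The transposon frame YLR035C-A was at least 27-fold lower.

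Heat shock and stress genes were lower in SWI3 S237A than in wild type, as in RPD3 KO. Here too, whether wild type stood high or the mutant low cannot be told. Of 25 chaperone genes 23 fell and 0 rose. Across its genes the median log2 was -2.61 and the camera adjusted p 1.46e-52 (1.94e-63 to 4.27e-46 over 9 alternatives, adjusted p = 0.00623 with an estimated correlation). HSP104 fell from 6390 ± 494 to 329 ± 10.9 CPM (log2 -4.28 ± 0.08), HSP82 from 3620 ± 295 to 135 ± 1.79 (log2 -4.74 ± 0.09), HSP78 to 105 ± 1.39 (log2 -3.90 ± 0.10) and the cyclophilin gene CPR6 from 1210 ± 18.5 to 175 ± 4.72 (log2 -2.79 ± 0.07), with adjusted p from 2.86e-12 to 1.16e-11. Of 36 Msn2 and Msn4 targets 36 fell. The median log2 was -3.05 and the camera adjusted p 4.18e-46 (1.9e-81 to 4.08e-43 over 9 alternatives, adjusted p = 0.0236 with an estimated correlation). Its members included GRE3 (log2 -3.04 ± 0.09), GSY1 (668 ± 91.3 to 47.7 ± 4.21 CPM, log2 -3.81 ± 0.11) and TSL1 (log2 -3.63 ± 0.12). The cell wall genes SED1 (3190 ± 108 to 156 ± 10.9 CPM, log2 -4.36 ± 0.10) and PST1 (log2 -2.38 ± 0.07) fell, in a list with 8 higher and 10 lower of 22 (adjusted p = 0.194).

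Sulfur, amino acid, nitrogen and sterol genes rose in SWI3 S237A. Of 23 sulfur and methionine genes 21 rose and 0 fell (median log2 1.3, camera adjusted p = 5.09e-21, 1.76e-22 to 4.37e-15 over 9 alternatives, adjusted p = 0.00623 with an estimated correlation), MET5 (log2 2.45 ± 0.08) and the sulfate transporter gene SUL2 (log2 2.26 ± 0.08) among them. Of 44 Gcn4 targets 42 rose and 1 fell. Here the median log2 was 0.94 and the camera adjusted p 7.85e-22 (5.5e-23 to 1.29e-19 over 9 alternatives, adjusted p = 0.0272 with an estimated correlation). Its members included the transaminase gene BAT1 (214 ± 17.9 to 1060 ± 61.3 CPM, log2 2.32 ± 0.08) and LYS21, of lysine synthesis (540 ± 42.8 to 2110 ± 86 CPM, log2 1.97 ± 0.08). Of 25 nitrogen genes 14 rose and 5 fell (15 and 5 when adjusted over the list alone). For this list the median log2 was 0.58 and the camera adjusted p 0.00176 (0.000817 to 0.0729 over 9 alternatives, adjusted p = 0.632 with an estimated correlation). Its members included the amino acid permease gene GAP1 (46.4 ± 10.7 to 316 ± 8.28 CPM, log2 2.77 ± 0.18), CAR1 (log2 2.32 ± 0.10), the ammonium permease gene MEP3 (log2 2.13 ± 0.12) and DUR3 (log2 1.22 ± 0.11). Without wild type replicate 1, whose nitrogen median was -0.25 against 0.09 and 0.16, the nitrogen call ended (adjusted p = 0.0729). Of 22 ergosterol genes 16 rose and 3 fell. As a list, the median log2 was 0.63 and the camera adjusted p 0.000325 (5.46e-05 to 0.000817 over 9 alternatives, adjusted p = 0.288 with an estimated correlation). Its members included ERG1 (257 ± 14.6 to 804 ± 15.7 CPM, log2 1.65 ± 0.07), ERG4 (log2 1.01 ± 0.06), ERG2 (log2 0.98 ± 0.08) and ERG7 (log2 0.92 ± 0.06).

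Ribosome biogenesis rose in SWI3 S237A, with 82 of 90 genes higher and 1 lower (84 and 1 when adjusted over the list alone). Over all members the median log2 was 0.99 and the camera adjusted p 1.26e-09 (2.48e-24 to 4.6e-08 over 9 alternatives, adjusted p = 0.773 with an estimated correlation). DBP10 (log2 1.38 ± 0.17), DBP7 (log2 1.3 ± 0.10), SPB1 (log2 1.3 ± 0.14) and NOP19 (log2 0.78 ± 0.10) rose. The ribosomal proteins had 8 higher and 39 lower of 138 (6 and 34 when adjusted over the list alone; median log2 -0.10, adjusted p = 0.585), with RPS14B falling (log2 -1 ± 0.10). Of the respiration genes 32 of 47 fell and 2 rose. Across its genes the median log2 was -0.60 and the camera adjusted p 0.00104 (3.51e-07 to 0.00616 over 9 alternatives, adjusted p = 0.773 with an estimated correlation). Its members included QCR8 (log2 -1.73 ± 0.09), ACO1 (log2 -1.16 ± 0.11), NDI1 (log2 -1.11 ± 0.11) and NDE1 (log2 -1.02 ± 0.10). The hexose transport list was not called (5 higher and 3 lower of 16, adjusted p = 0.846), with a median of 0.33 and a mean of -0.39, and HXT4 fell (log2 -3.73 ± 0.21).

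In SWI3 S237A 11 of 15 daughter separation genes fell and 2 rose. The median log2 was -0.60 and the camera adjusted p 0.0193 (0.0181 to 0.11 over 9 alternatives, adjusted p = 0.276 with an estimated correlation). Its members included PCL9 (log2 -1.56 ± 0.09), RME1 (log2 -1.42 ± 0.10), EGT2 (log2 -1.11 ± 0.10) and DSE3 (log2 -0.74 ± 0.07). Of 24 G1/S genes 16 rose and 3 fell. Here the median log2 was 0.39 and the camera adjusted p 0.0392 (0.0149 to 0.245 over 9 alternatives, adjusted p = 0.773 with an estimated correlation). Its members included RNR1 (log2 1.09 ± 0.13) and PRI2 (log2 0.80 ± 0.08). Of 22 thiamine and vitamin genes 13 rose and 2 fell. For this list the median log2 was 0.43 and the camera adjusted p 0.032 (0.0314 to 0.236 over 9 alternatives, adjusted p = 0.224 with an estimated correlation). Its members included THI12 (log2 3.31 ± 0.32) and THI7 (log2 1.32 ± 0.07). Without wild type replicate 1 these 3 calls ended, with adjusted p of 0.11, 0.245 and 0.236. Under total counts only the G1/S (0.0514) and thiamine (0.0504) calls ended as well. Early meiotic genes, raised in RPD3 KO, had 5 higher and 3 lower of 24 in SWI3 S237A (3 and 2 when adjusted over the list alone; adjusted p = 0.585), with DMC1 rising (log2 1.21 ± 0.14). The iron regulon had 9 higher and 9 lower of 26 (10 and 9 when adjusted over the list alone; adjusted p = 0.846), with TIS11 falling (log2 -2 ± 0.13) and FET5 rising (log2 0.87 ± 0.06). TIR1 fell (log2 -3.40 ± 0.14), and of the alpha-specific genes MF(ALPHA)2 (log2 -2.34 ± 0.15) and SAG1 (log2 -1.41 ± 0.16) fell, 3 lower and 1 higher of 5 (adjusted p = 0.195). The a-specific genes had 1 higher and 1 lower of 5, and the haploid-specific genes 1 higher and 7 lower of 10 (adjusted p = 0.0512). The haploid-specific list passed under RLE (0.0498) and without wild type replicate 1 (0.0105) or 17 (0.0483) or SWI3 S237A replicate 2 (0.04).

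Of 35 lists 11 were called in SWI3 S237A, 7 up and 4 down, 4 of them with an estimated correlation. Subunits of SWI/SNF had 3 higher and 4 lower of 12, with SNF2 rising (log2 0.47 ± 0.09, adjusted p = 0.000557), and subunits of the Rpd3 complexes 1 higher and 6 lower of 14, with ASH1 falling (log2 -0.72 ± 0.08, adjusted p = 5.54e-06). Values of SWI3 S237A and wild type did not overlap in 4193 genes (66.3%, where 10% is the share given by chance). Which direction prevails rests on the scaling. Of the called genes 47.8% were higher under TMM, 50.6% under RLE, 51.7% under upper-quartile scaling and 53.3% under total counts only. Of the called genes 201 were not in the reference used and 246 shared over 5% of their words. The authors' deposited table called 3404 genes, 1691 up and 1713 down, of which 3338 were also called here with the same sign (Pearson r = 0.977). That table held no adjusted p for OLE1, and its adjusted p was 0.0654 for YAR010C and for YPR137C-A.

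RPD3 S418A and RPD3 KO were compared directly. RPD3 itself was at least 792-fold higher in RPD3 S418A. HSP104 stood at 6290 ± 172 CPM against 123 ± 1.47 (log2 5.67 ± 0.09, adjusted p = 1.01e-13), HSP82 at 3380 ± 271 against 115 ± 5.73 (log2 4.88 ± 0.10), HXT7 at 3410 ± 457 against 12.1 ± 2.45 (log2 8.14 ± 0.28) and HXK1 at 4010 ± 319 against 29.3 ± 2.79 (log2 7.10 ± 0.37). NSR1 stood at 40 ± 10.7 against 1430 ± 57.6 (log2 -5.16 ± 0.41), DHR2 at 1.66 ± 0.468 against 119 ± 3.4 (log2 -6.13 ± 0.57) and the helicase gene HCA4 at 8.28 ± 3.2 against 260 ± 5.32 (log2 -4.95 ± 0.56). In all, 4602 genes differed, 2496 higher and 2106 lower in RPD3 S418A, 863 and 828 of them by at least 2-fold. Among end-proximal genes COS10 was higher (log2 8.11 ± 0.52), and so was PHO11 (log2 7.67 ± 0.93, and 12.71 without RPD3 KO replicate 4). The size for COS10 is uncertain, since its RPD3 KO value lies under the floor of 3 counts per library. The mean difference between the outer 20 kb and the rest of the arm was 1.8 over 21 chromosome ends (permutation p = 0.00015, adjusted p = 3e-04). RPD3 itself, within 20 kb of an end of chromosome XIV, was not left out of this difference.

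This direct comparison shares the 3 RPD3 KO libraries with the comparison against wild type, so opposite signs in the 2 are largely set by that. Chaperones were higher in 23 of 25 genes (median 2.26, camera adjusted p = 2.03e-31, 1.35e-36 to 2.38e-16 over 9 alternatives, adjusted p = 0.0383 with an estimated correlation), Msn2 and Msn4 targets in 35 of 36 (median 3.18, 4.88e-28, 1.14e-30 to 4.47e-21 over 9 alternatives, adjusted p = 0.143 with an estimated correlation) and respiration genes in 44 of 47 with 1 lower (median 1.5, 4.76e-12, 1.94e-14 to 2.17e-11 over 9 alternatives, adjusted p = 0.578 with an estimated correlation). Ribosome biogenesis was lower in 90 of 90 (median -2.60, 2.58e-25, 7.7e-31 to 1.64e-23 over 9 alternatives, adjusted p = 0.578 with an estimated correlation). The iron regulon had 3 higher and 22 lower of 26 (median -0.98, 2.66e-10, 2.43e-11 to 1.53e-08 over 9 alternatives, adjusted p = 0.154 with an estimated correlation). Its members included FIT2 at 13.9 ± 1.1 against 257 ± 27.7 CPM (log2 -4.21 ± 0.13), FIT1 (log2 -3.96 ± 0.15) and ARN2 (log2 -2.03 ± 0.08). Early meiotic genes had 1 higher and 21 lower of 24 (median -1.3, 0.000223, 0.000101 to 0.00102 over 9 alternatives, adjusted p = 0.574 with an estimated correlation), MND1 (log2 -3.51 ± 0.26) and ZIP1 (log2 -1.61 ± 0.11) among them. Alpha-specific genes were higher in 5 of 5 (median 2.02, 0.000921, 0.000391 to 0.00181 over 9 alternatives, adjusted p = 0.556 with an estimated correlation), and hexose transport had 11 higher and 3 lower of 16 (median 1.64, 0.00278, 0.00102 to 0.00904 over 9 alternatives, adjusted p = 0.154 with an estimated correlation).

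In RPD3 S418A against RPD3 KO phosphate genes had 16 higher and 2 lower of 20 (median 1.08, adjusted p = 0.0106, 0.00358 to 0.0121 over 9 alternatives, adjusted p = 0.578 with an estimated correlation). Its members included PHM8 at 125 ± 8.92 against 15.3 ± 1.4 CPM and GIT1 at least 27-fold higher. Cell wall integrity genes had 14 higher and 5 lower of 22 (6 lower when adjusted over the list alone; median 0.62, adjusted p = 0.0386, 0.0304 to 0.0458 over 9 alternatives, adjusted p = 0.629 with an estimated correlation). Its members included YPS6 (log2 4.91 ± 0.19) and the kinase gene SLT2 (log2 1.91 ± 0.12). G1/S genes had 2 higher and 18 lower of 24 (median -0.83, adjusted p = 0.00176, 0.000534 to 0.00265 over 9 alternatives, adjusted p = 0.578 with an estimated correlation) and G2/M genes 0 higher and 11 lower of 15 (median -0.50, adjusted p = 0.0386, 0.0181 to 0.0443 over 9 alternatives, adjusted p = 0.629 with an estimated correlation). Ergosterol genes had 6 higher and 15 lower of 22 (median -0.55, adjusted p = 0.0386, 0.0135 to 0.0484 over 9 alternatives, adjusted p = 0.625 with an estimated correlation). Its members included ERG3 (log2 -2.44 ± 0.17). Galactose and maltose genes had 10 higher and 2 lower of 13 (median 1.11, adjusted p = 0.0472, 0.0543 without RPD3 S418A replicate 3, and 0.578 with an estimated correlation). Gcn4 targets had 6 higher and 22 lower of 44 (median -0.30, adjusted p = 0.0472, 0.0695 without RPD3 KO replicate 20, 0.105 without RPD3 S418A replicate 3, and 0.629 with an estimated correlation). Genes repressed by glucose had 4 higher and 17 lower of 27 (median -0.51, adjusted p = 0.0472, 0.0589 and 0.0712 without RPD3 S418A replicates 3 and 11, 0.0535 under RLE, 0.0852 under total counts only, and 0.629 with an estimated correlation).

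Of 35 lists 16 were called in the direct comparison, 8 up and 8 down, and 1 with an estimated correlation. Values did not overlap in 4850 genes (76.7%, where 10% is the share given by chance). Under total counts only the share of higher genes moved from 54.2% to 42.6%, a median shift of -0.171, with 20 called genes changing sign.

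The changes of the 3 mutants against wild type were set beside each other, first for RPD3 KO and SWI3 S237A. HSP104, HSP82 and HXT7 fell and OLE1, CAR1 and DBP7 rose in both. Across 6327 genes the correlation of log2 fold changes was 0.40 for RPD3 KO and SWI3 S237A (Spearman 0.53). Simulated unchanged groups that share the 3 wild-type libraries gave 0.50 (Spearman 0.47). With no changed genes the simulated value reflects noise alone, so the correlation cannot be judged against it where many genes changed. The covariance was 0.529 against 0.027 simulated, a difference of 0.501. Of genes called in both, 1131 rose in both and 1322 fell in both, where independent calls give 579.2 and 754.4, and 179 and 276 had opposite signs, where independent calls give 632.5 and 690.9. Part of any excess can come from the shared wild-type libraries, which were not split between the comparisons, as 1 part would hold a single library.

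FIT2 and FIT3, which fell in RPD3 S418A, also fell in SWI3 S237A (log2 -1.62 and -1.42), and so did TIS11 and TIR1. With RPD3 KO the correlation of RPD3 S418A was -0.06 (Spearman -0.28, simulated 0.50; covariance difference -0.063), with FIT2 rising in RPD3 KO and falling in RPD3 S418A. Both rose in 13 genes and fell in 34, against 16.6 and 28.9 for independent calls, and opposite signs were found in 30 and 33 genes, against 24.2 and 19.8. With SWI3 S237A the correlation was 0.20 (Spearman -0.30, simulated 0.49; covariance difference 0.074), with 13 rising and 26 falling in both, against 14.9 and 23.8, and 29 and 35 of opposite sign, against 16.3 and 21.8. MET6 rose in both (log2 0.61 and 2.66), and SED1 rose in RPD3 S418A (log2 0.45) and fell in SWI3 S237A (log2 -4.36). Among 5377 genes with few shared words the 3 correlations were -0.19 for RPD3 KO and RPD3 S418A, 0.55 for RPD3 KO and SWI3 S237A, and -0.22 for RPD3 S418A and SWI3 S237A. For that last pair the covariance difference was -0.064, so its positive value rested on the genes left out there, which share words or are not in the reference. The transposon frames had mean log2 values of 0.84 in RPD3 S418A and 1.72 in SWI3 S237A, with medians of -0.34 and -0.43. The simulated correlations hold no changed genes, so those of RPD3 S418A cannot be judged against them either.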

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

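The run on genes with few shared words was chosen only after the result was seen. Counts of changed genes in RPD3 KO, SWI3 S237A and RPD3 S418A against RPD3 KO stayed within 1.5 times under every other alternative, and fell to 1504 (714 up, 790 down), 854 (398 up, 456 down) and 1691 (863 up, 828 down) with an absolute log2 fold change of at least 1, which by construction keeps fewer genes. The 128 genes of RPD3 S418A became 27 (5 up, 22 down) that way, 51 (17 up, 34 down) at an adjusted p under 0.01, 29 (8 up, 21 down) with the compared groups only and 314 (134 up, 180 down) with DESeq2, and ran from 60 without RPD3 S418A replicate 19 to 272 without wild type replicate 1. The cause was not tested. With estimated correlations, called lists fell from 11, 13, 11 and 16 to 1, 4, 4 and 1 in RPD3 KO, RPD3 S418A, SWI3 S237A and RPD3 S418A against RPD3 KO.

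Correlations of log2 fold changes moved with the genes used. For RPD3 KO and RPD3 S418A the value was -0.06, against -0.28 by Spearman, -0.196 with at least 10 CPM, -0.194 with few shared words, and -0.085 without RPD3 S418A replicate 3 to 0.041 without wild type replicate 1, which reversed it. For RPD3 KO and SWI3 S237A it was 0.397, against 0.53 by Spearman, 0.547 with at least 10 CPM, 0.553 with few shared words, and 0.38 to 0.439 with a library left out. For RPD3 S418A and SWI3 S237A it was 0.201, against -0.304 by Spearman and -0.221 with few shared words, both reversed, and 0.164 to 0.267 with a library left out. The positive sign for that pair rested on genes with shared words or not in the reference. Why the other values moved was not tested.

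The ratio of RPD3 in SWI3 S237A to wild type was 0.84, and 0.91 by TPM. The ratio of SWI3 in RPD3 KO was 1.25, and 1.41 by total counts and 1.43 by TPM; in SWI3 S237A it was 1.07, and 1.17 by TPM. AAD14 in RPD3 KO, which did not pass, went from -0.03 to 0.02 under RLE, the compared groups only and DESeq2, to 0.15 by total counts, and ran from -0.11 without wild type replicate 9 to 0.06 without wild type replicate 17. The cause was not tested. The label numbers were not taken to pair the samples, as 4 of 18 same-number pairs had a correlation over 0.1 (range -0.12 to 0.27). Still, 19 of 36 choices favoured the own number, above the 1 in 3 of chance, so a weak pairing is not ruled out. The replicate block gave 4455, 147, 3867 and 4627 genes in the 4 comparisons. Under it the calls of FET3 (adjusted p = 0.0837) and HXT6 (0.0755) in RPD3 S418A ended. In SWI3 S237A those of YDR098C-A (0.142), YML045W-A (0.0754), YDR316W-A and YGR161C-C (0.0778 each) ended, and so did that of the thiamine and vitamin list (camera adjusted p = 0.0527). Lists that gained a call included pheromone response (0.0472) and galactose (0.0444) in RPD3 KO and the haploid-specific genes (0.0496) in SWI3 S237A. Depth limits what can be seen under 0.109 to 0.169 CPM.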

Other observations

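The tests of explanations below were chosen only after the results were seen. Among groups not yet described, histone genes had 7 of 11 higher and 0 lower in RPD3 KO (median log2 0.42, camera adjusted p = 0.202) and in SWI3 S237A (median 0.29, camera adjusted p = 0.276). Proteasome genes had 16 of 33 lower and 0 higher in RPD3 KO (median -0.15, camera adjusted p = 0.426), with PRE3 falling (log2 -0.58), and 7 higher and 6 lower in SWI3 S237A. Flocculation genes had 7 of 11 higher and 2 lower in SWI3 S237A (median 0.69, camera adjusted p = 0.0553), where FLO1 rose (log2 1.36), and 3 higher and 6 lower in RPD3 KO, where FLO1 fell (log2 -1.45). Subunits of SWI/SNF had 4 higher and 4 lower of 12 in RPD3 KO. In RPD3 S418A no member of these 4 lists passed over all genes with edgeR.

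Chaperone and stress genes were high in wild type and RPD3 S418A and low in RPD3 KO and SWI3 S237A, with HSP104 at 6390, 6290, 123 and 329 CPM. For RPD3 KO a state of the wild-type libraries alone did not account for this, since the chaperone median was 2.26 in RPD3 S418A against RPD3 KO, which uses no wild-type library. That value largely follows from the medians against wild type, -2.32 in RPD3 KO and -0.08 in RPD3 S418A. No such comparison was run for SWI3 S237A. Scaling did not account for the fall in RPD3 KO either, with a chaperone median of -2.15 under total counts only. A growth-rate difference that moves ribosomal protein and ribosome biogenesis genes together predicted a shift of the ribosomal proteins, whose median in RPD3 KO was 0.004, with 107 of 138 within 0.25 of 0. The labels' protocols describe caffeine for part of the samples, while each of the 12 libraries used here is labelled synthetic defined medium. A difference in culture, or in a treatment that the labels do not show, stays open for this pattern, and could lie in the strains with high or in those with low levels. It was not tested, and it bears on what these values mean.

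Wild type replicate 1 stood apart from replicates 9 and 17, with a chi-square per degree of freedom of 104.66 and 121.18 against 9.08 between those. Its depth of 23.3 M lay inside the range of the other libraries. A batch shared by its whole number set was not seen, with a median correlation of 0.03 with the set's other libraries (0.02, 0.03 and 0.21), while one shared with RPD3 S418A replicate 3 alone, the library at 0.21, stays open. RNA of an RPD3 KO library mixed in would have needed a share of 19.6%, by the median of the ribosome biogenesis genes. That share would have left RPD3 at 0.80 of the other replicates, where 0.93 was found. The level of RPD3 cannot exclude a smaller share. The cause was not found.

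Genes near chromosome ends were lower in RPD3 KO. Reads shared between gene copies did not account for this, since genes with few shared words within 10 kb of an end had a median log2 of -3.23 against -0.04 farther than 100 kb. Low expression did not account for all of it, as the 97 genes with few shared words within 20 kb had a median of -1.68, and 0 of 10000 lists matched on expression were as low (-0.39 to 0.30). Among those with a mean of at least 10 CPM the fall was smaller, with a median of -1.87 in 10 genes within 10 kb and -0.42 in 51 genes at 10 to 20 kb, so how far its size depends on expression stays open. The deleted gene RPD3, at 10 to 20 kb from an end, was not left out of the genes within 20 kb.

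Dividing the 6 libraries of each comparison in all 10 ways into 3 and 3, the real division called 4425, 128, 3799 and 4602 genes in RPD3 KO, RPD3 S418A, SWI3 S237A and RPD3 S418A against RPD3 KO, and the highest other division 0 by edgeR, with up to 370, 1250, 492 and 206 genes at an unadjusted p under 0.05. The real divisions had 4595, 1142, 4062 and 4730 such genes, so in RPD3 S418A another division had more than the real one. In each comparison 1 of 10 divisions, the real one, reached its count of called genes, and 10 are too few for a share under 0.05. Every other division put libraries of both strains in each part, so differences between the strains entered the spread and made calls hard to reach. The counts of 0 therefore do not show how many calls would arise without a strain difference.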
